A study of Mus musculus with 204 samples.

How the data were processed

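The series comprised RNA sequencing libraries of 21 tissues from male C57BL/6J mice, DIO after 10 weeks on a diet with 60% fat or lean on chow with 13.1% fat. Per the labels, libraries were made with the TruSeq stranded mRNA kit and sequenced on a HiSeq 2000 as paired reads. The submitters' processing notes name FastQC, STAR, HTSeq and DESeq2; their versions and settings are not given in the sources used here. The labels were inconsistent on the age of the mice and on the number of tissues, and the identifiers of DIO and lean libraries came from different series of names in colon and cerebral cortex.

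The deposited table held CPM for 13154 genes and 205 columns. One column matched no sample and was not used, and 1 incomplete gene was left out, which left 13153 genes (3158 of them with no read) and 204 libraries. Whole reads could be recovered from every library: 100% of values were whole within 0.001 read, and the totals of 204 libraries were whole. The table held between 13.0% and 23.1% of the reads of a library (median 19.1%), because it ran through chromosomes 1, 2, X and 3 (3435, 3793, 2614 and 2884 genes of 3445, 3803, 2614 and 2885 annotated) and ended 40.3 Mb into chromosome 4 (413 of 2873 genes). GENCODE M21 held 13139 of the gene identifiers and not the other 14; 46 shared a symbol with another. Genes elsewhere in the genome were not analysed here. Within tissues and diets 398 pairs of replicates were compared by chi-square per degree of freedom (lowest 4.21, median 46.8), and none was counted as a duplicate.

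In each tissue, DIO was compared with lean by limma with a mean-variance trend on log2(CPM + 1) over genes with a mean of at least 10 CPM, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The filter had been written for normalised counts and was applied as it stood to CPM. The fold on this scale understates changes of genes at a few CPM. Differences of the diet effect between tissues were tested by an F test of diet by tissue in limma for white fat depots, skeletal muscles, intestine segments and brain regions. Of 49 gene lists (such as macrophage, extracellular matrix, fatty acid oxidation, cholesterol synthesis and oxidative phosphorylation) fixed with 352 pairs of list and tissue, pairs with at least 3 tested members were tested by fry. For genes shared across tissues, calls were shuffled within each tissue 1000 times. Genes were named by a fixed rule: in a tissue the 4 largest rises and the 4 largest falls among genes past the threshold with at least 50 CPM in the higher group and full separation, or else the 2 of lowest p. Up to 4 members per described list were also named, and so were the 12 genes that recurred in most tissues and 4 per interaction. Single values of some genes that this rule takes are not reported here, while all tests and counts of genes keep them. The groups, these tests, the lists, the naming rule, the label check genes and the alternatives that open the next paragraph were set before the data were examined.

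Alternatives were a pseudocount of 5, no filter, rescaling by median-of-ratios factors within the tissue, array weights, a single fit over all libraries, edgeR and DESeq2 on the recovered reads, each library left out in turn, an exact permutation test for lists, and other minimum numbers of tissues for shared genes. After the data were seen, 5 more were added: leaving out 16 libraries with the marker of another tissue or a loss of their own, a covariate, a class term, a term for the largest gap of Ttn in soleus and heart, and the log2 level of Ttn as a covariate in brown fat. The first covariate was an index of 10 genes (the mean log2 level of Rpl22l1, Ndufc1, Atp5e, Cops9 and Rpl39 minus that of S100a1, Kantr, Dynlrb1, Ubap2l and Ncoa6). It was run first and took liver from 458 to 57 genes. The class term, which parted the libraries of 11 tissues at a gap of at least 0.75 in the index with at least 2 libraries on each side, was set after that result was in view; a gap of 1 had been considered first. Heart had the largest gap (2.27), but it set lean 5 alone apart, so heart was not parted. Both are reported.

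The tests were tried on simulated reads with known changes at 3 fold sizes. In subcutaneous fat limma recovered 15.2%, 41.8% and 92.3% of genes changed 1.5, 2 and 4 times, in mesenteric fat 20.9%, 79.1% and 100%, in liver 95.5%, 97.0% and 100%, and in duodenum 53.7%, 91.0% and 95.5%. In the intestine interaction it recovered 29.9%, 85.1% and 100%, with 9.49% of calls false. In the 4 tissues between 3.92% and 5.88% of limma calls, 3.00% and 5.37% of edgeR calls and 8.49% and 12.4% of DESeq2 calls were false. Simulated genes varied independently of each other, without library classes, a gap of Ttn or admixed tissue, so these rates need not hold in the real libraries. In duodenum the simulation without changes called 0 genes by limma, while another split of the real libraries called 1059. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.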

Results

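RNA was sequenced from 21 tissues of male C57BL/6J mice, an inbred strain that gains weight on fat-rich food. The mice were either diet-induced obese (DIO) after 10 weeks on a diet with 60% fat, or lean on chow with 13.1% fat. There were 5 DIO and 5 lean libraries per tissue, except for subcutaneous fat (3 DIO, 5 lean), mesenteric fat (4 DIO, 3 lean) and the extensor digitorum longus muscle (EDL; 5 DIO, 4 lean). Library totals ranged from 6.58 to 129.7 M reads with a median of 20.7, the largest being the epididymal fat (eWAT) DIO 3 library and the next largest 30.9. The deposited values covered genes on chromosomes 1, 2, X and 3 and the start of chromosome 4, which was 23.7% of annotated mouse genes, so every count below refers to those genes. Levels are given as mean ± SD in counts per 1000000 reads (CPM), DIO against lean. Changes are given as log2 of DIO over lean ± standard error, from limma on log2(CPM + 1), with p adjusted over the genes tested in that tissue. These p-values measure the spread between libraries. The labels do not tie libraries of different tissues to mice, and since the series was designed with 5 lean and 5 DIO mice the tissues probably share mice, so results in different tissues are not independent.

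Genes that mark single tissues were high in the libraries labelled so. Apoa2, a liver apolipoprotein, averaged 5312 CPM in liver, and Car1, a carbonic anhydrase of the large bowel, averaged 8673 CPM in colon and at most 3.84 CPM on average elsewhere. Fabp2, an intestinal fatty acid carrier, averaged 2140 CPM in duodenum, 9424 CPM in jejunum and 2646 CPM in ileum. Snap25, a synaptic protein, lay between 1438 and 3257 CPM in every library of the 4 brain regions. Oxt, the oxytocin precursor, averaged 24.1 CPM in hypothalamus but spanned 0.158 to 48.0 CPM there, and Wt1, a mesothelial and kidney transcription factor, averaged 18.7 CPM in mesenteric fat and 10.4 CPM in kidney. Apoa2 reached 3651 CPM in an adrenal library. These 6 were the only ones of 28 label check genes present in the table. By rank correlation over genes with a mean of at least 1 CPM over all libraries, 192 libraries had their best match in their own tissue. The rest were the 3 adrenal libraries named next and libraries of eWAT, retroperitoneal and mesenteric fat. Each of these fat libraries matched another fat depot best. In 3 adrenal libraries (DIO 1, DIO 2 and lean 1) the steroid-making enzyme Hsd3b1 was at 0.173, 0.0833 and 0 CPM, against 4239 to 12650 CPM in the other adrenal libraries.

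By limma with all libraries weighted alike and each tissue fitted alone, most changes with diet lay in white and brown fat, liver, jejunum and 2 muscles. The number of genes past adjusted p 0.05 was 1166 in eWAT, 1002 in mesenteric fat, 957 in retroperitoneal fat, 770 in brown fat, 458 in liver, 274 in subcutaneous fat, 205 in jejunum, 83 in red gastrocnemius and 29 in soleus. Each of the other 12 tissues had 6 or fewer by that fit. Other settings gave more in some of them: array weights 1212 in stomach, 811 in heart, 795 in duodenum and 530 in colon, a single fit over all libraries 677 in adrenal, 336 in stomach and 328 in duodenum, and the fit without the lean 3 library 806 in duodenum. Among genes that passed, those named below for a tissue were the largest rises and falls with every DIO library on one side of every lean library and at least 50 CPM in the higher group. In eWAT 39.9% of tested genes were separated in that way against 0.79% by chance for 5 and 5 libraries. The separated share was 63.5% in mesenteric fat (chance 5.71%), 34.8% in retroperitoneal fat, 32.5% in subcutaneous fat (chance 3.57%), 30.8% in brown fat, 17.5% in liver, 10.0% in jejunum, 6.34% in red gastrocnemius and 4.02% in soleus. It was above that of soleus in adrenal (4.65%), colon (4.5%) and kidney (4.04%), where few or no genes passed. Duodenum had 2.84%, heart 2.17% and the remaining tissues at most 0.75%.

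**Figure D1:**
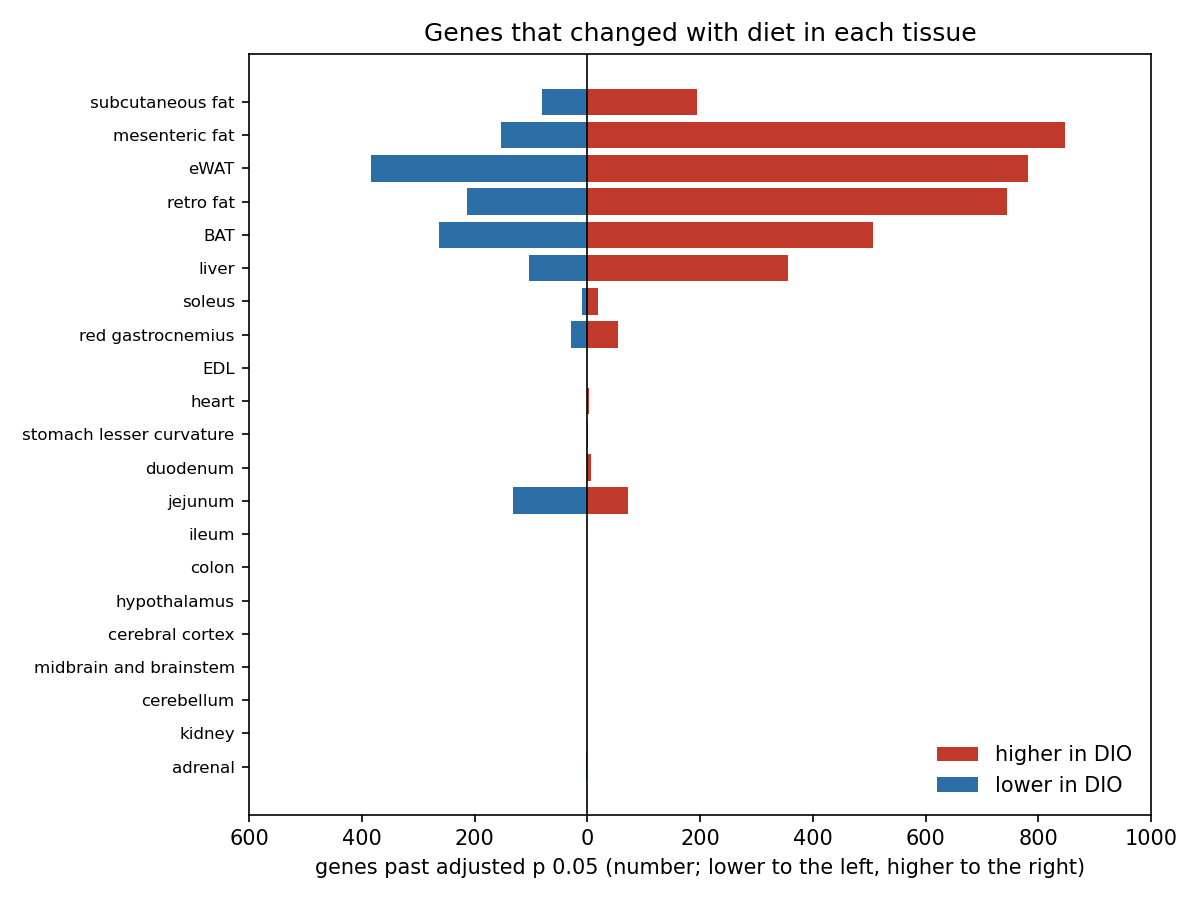
Genes past adjusted p 0.05 (number) in each of the 21 tissues, lower in DIO to the left and higher in DIO to the right. The fat depots and liver hold the longest bars.

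In subcutaneous fat (3 DIO, 5 lean libraries) the 2 tested genes of fatty acid synthesis fell, and genes of the extracellular matrix rose. Elovl6, which elongates fatty acids, was at 44.0 ± 9.13 against 577 ± 427 CPM (-3.42 ± 0.53, adjusted p 0.00677). Hsd11b1, which regenerates active glucocorticoid, was at 88.3 ± 19.0 against 409 ± 87.6 CPM (-2.20 ± 0.21), Slc43a1, an amino acid transporter, changed by -2.52 ± 0.30, and Dennd2d by -2.98 ± 0.68 (adjusted p 0.0776 with an index of 10 genes as a covariate, chosen after the data were seen). Lbp, which binds bacterial lipopolysaccharide, rose to 529.8 ± 37.8 from 49.8 ± 41.7 CPM (3.80 ± 0.65, adjusted p 0.0102), and the matrix proteoglycan Prelp to 2026 ± 88.0 from 380.1 ± 202 CPM (2.60 ± 0.47). Trp53inp2, an autophagy regulator, changed by 2.84 ± 0.39 and Map1a, a microtubule protein, by 3.33 ± 0.42. Of 6 tested extracellular matrix genes, 3 rose, 0 fell and 3 did not pass (5 rose when adjusted over the list alone), with Postn at 1.96 ± 0.24, Thbs1 at 2.10 ± 0.32 and Col6a3 at 1.83 ± 0.34 (list test adjusted p 0.0174). Of 3 endothelial genes 1 rose, Eng at 0.89 ± 0.13, and 3 rose over the list alone (adjusted p 0.0266), which ended on the rescaled scale (0.0898), without the lean 2 and lean 3 libraries (0.0752) and with that covariate (0.0850). The complement receptor Cr2 was at 146.6 CPM in the lean 2 library and 146 CPM in the lean 3 library, against 0.0715 to 0.712 CPM in the others of this depot. In all, 194 genes rose and 80 fell out of 2198, and 972 passed without those 2 libraries, while 64, 73, 76 and 168 passed without DIO 1, DIO 2, DIO 3 or lean 2.

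In mesenteric fat (4 DIO, 3 lean libraries) macrophage genes rose and genes of fatty acid and cholesterol synthesis and of the respiratory chain fell. The median of all genes was higher in DIO by 0.403, so changes are given relative to the other genes of each library (rescaled) in this paragraph, while counts of list members are those before rescaling, here and below. Elovl6 was at 41.2 ± 10.4 against 1645 ± 355 CPM (-5.71, adjusted p 7.0e-05), Acss2, which makes acetyl-CoA from acetate, at 178 ± 28.2 against 1485 ± 111 CPM (-3.47), Tmem79 at -4.54 and the peptidase Enpep at -3.05. The 4 tested macrophage genes all rose, over the list alone too, with Atp6v0d2, a proton pump subunit of macrophages and osteoclasts, at 51.5 ± 19.9 against 0.621 ± 0.107 CPM (4.66), and the lysosomal protease Ctss at 461 ± 98.0 against 43.8 ± 10.2 CPM (2.96). The others were Fcer1g at 1.49 and Mrc1 at 0.96 (list test adjusted p 4.0e-04 before and 0.00105 after rescaling). The leukocyte receptor Cd84 changed by 2.76 and the protease Ctsk by 2.39. All 8 tested oxidative phosphorylation genes fell, over the list alone too, among them Ndufb5 at -0.90 and Cox5b at -0.95 (list test adjusted p 0.00117 after rescaling). Of 4 cholesterol synthesis genes 2 fell, 0 rose and 2 did not pass, and 2 fell over the list alone, with Pmvk at -1.95 and Nsdhl at -1.82 (list test 2.7e-04 after rescaling). Ebp of that list turned from 0.03 (adjusted p 0.733) to -0.37 (adjusted p 0.0251) with rescaling. Extracellular matrix genes (5 of 6 rose, 5 over the list alone, adjusted p 0.0174) and interferon genes (3 of 6 rose, 3 over the list alone, adjusted p 0.0402) passed only before rescaling (0.0898 and 0.530). Nor did the interferon list pass without DIO 2 (0.0672) or with no filter (0.0582), or the matrix list with the index of 10 genes as a covariate (0.0540). Cr2 was at 268.8 CPM in the DIO 2 library and at 0.566 to 4.98 CPM in the others. Of 2232 genes 848 rose and 154 fell, against 192 and 369 after rescaling; 1505 passed without DIO 2, and 443, 468 and 531 without lean 1, lean 2 or lean 3.

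In eWAT (5 DIO, 5 lean) macrophage and extracellular matrix genes and 2 of 3 inflammatory mediators rose, while respiratory chain genes and the 2 tested adipocyte genes fell. The median shift was 0.172, and changes here are rescaled. Atp6v0d2 was at 493 ± 213 against 3.34 ± 3.05 CPM (6.75, adjusted p 2.4e-07) and Vsig8 at 78.0 ± 47.6 against 0.220 ± 0.165 CPM (5.67). Rgs1, a leukocyte regulator of G-protein signalling, was at 5.60, and Il1rn, the interleukin 1 receptor antagonist, at 106 ± 69.2 against 0.878 ± 0.564 CPM (5.51). Falls were led by the adhesion receptor Adgrg2 at 4.64 ± 2.62 against 88.4 ± 61.8 CPM (-3.93), Hsd11b1 at -3.25, the glutathione transferase Gsta3 at -3.18 and Pck1, a step of glyceroneogenesis, at 309 ± 211 against 2244 ± 894 CPM (-3.17). All 4 tested macrophage genes and all 7 extracellular matrix genes rose, over the lists alone too, among them Ctss (4.64), Fcer1g (2.93), Mrc1 (2.01), Timp1 (4.16), Postn (2.19) and Fn1 (2.16). Their list tests were at adjusted p 1.4e-04 and 1.5e-04 after rescaling. Of 3 inflammatory mediators 2 rose, 0 fell and 1 did not pass, and 2 rose over the list alone (adjusted p 2.3e-04), with Il1rn and Vcam1 (0.94) past the threshold and Lcn2 at -0.30 (adjusted p 0.821). Of 8 oxidative phosphorylation genes 7 fell, 0 rose and 1 did not pass, and 7 fell over the list alone, for example Ndufs3 at -0.84, Atp5c1 at -0.87 and Cox5b at -0.85 (2.7e-04). The adipocyte genes Fabp4, a fatty acid carrier, at 6858 ± 2664 against 14770 ± 2341 CPM, and Irs1, an insulin receptor substrate, at 22.9 ± 4.63 against 79.5 ± 5.60 CPM, both fell (adjusted p 0.00142 and 3.4e-07). Of 2155 genes 782 rose and 384 fell, against 589 and 584 after rescaling.

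Retroperitoneal fat (5 DIO, 5 lean) shared 618 of its 736 rises and 195 of its 207 falls with eWAT, among genes tested in both. With a median shift of 0.248, rescaled changes were 5.72 for Atp6v0d2 (226 ± 53.8 against 3.18 ± 2.51 CPM, adjusted p 3.9e-07), 4.81 for Rgs1, 4.81 for Il1rn (58.2 ± 36.3 against 0.766 ± 0.671 CPM) and 4.40 for Tlr13, a receptor for bacterial RNA. Elovl6 fell to 29.6 ± 6.98 from 314 ± 107 CPM (-3.59, adjusted p 1.5e-06), Acss2 to 166 ± 52.8 from 892 ± 132 CPM (-2.76), and the changes of Gsta3 and the long non-coding RNA Snhg11 were -3.07 and -2.43. The 4 macrophage genes rose, over the list alone too, with Ctss at 949.6 ± 734 against 46.3 ± 15.7 CPM (3.87), Fcer1g at 2.58 and Mrc1 at 2.02 (list test adjusted p 1.4e-04 after rescaling). Of 6 extracellular matrix genes 5 rose, 0 fell and 1 did not pass (6 rose over the list alone), with Thbs1 at 2.04, Col6a3 at 1.32 and Col3a1 at 1.24 (adjusted p 0.00832 after rescaling). Fabp4 was at 8954 ± 2010 against 16530 ± 6087 CPM (adjusted p 0.00883) and Irs1 at -1.34 (adjusted p 8.8e-05). Counts were 744 rises and 213 falls out of 2123 genes, and 413 of 805 were rises after rescaling. The T-cell gene Cd2 was at 35.2 CPM in the DIO 3 library and the fast-muscle gene Tnnc2 at 77.1 CPM in lean 2, against 1.93 to 3.94 CPM and 0.179 to 12.2 CPM in the other 8 libraries.

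In brown fat (BAT; 5 DIO, 5 lean) genes of fatty acid and cholesterol synthesis fell, and endothelial and matrix genes rose. Acss2 fell to 305 ± 69.7 from 974 ± 236 CPM (-1.67 ± 0.18, adjusted p 3.3e-05) and Elovl6 to 651 ± 153 from 1839 ± 354 CPM (-1.51 ± 0.18). Glul, which makes glutamine, fell to 674 ± 103 from 1807 ± 287 CPM (-1.42 ± 0.13) and Hsd11b1 changed by -1.27 ± 0.19. Pmepa1, a brake on TGF-beta signalling, rose to 453 ± 22.8 from 99.0 ± 20.0 CPM (2.20 ± 0.11) and Prelp to 831 ± 114 from 215 ± 39.2 CPM. The nucleotide exchange factor Arhgef2 rose to 76.8 ± 11.3 from 23.6 ± 2.93 CPM and the iron exporter Slc40a1 to 56.0 ± 7.79 from 18.4 ± 8.14 CPM (1.63 ± 0.23). All 3 tested cholesterol synthesis genes fell, over the list alone too: Pmvk at -1.14 ± 0.12, Nsdhl at -0.90 ± 0.12 and Ebp at -0.25 ± 0.07 (list test adjusted p 1.7e-04). Ebp did not pass without the DIO 5 and lean 2 libraries (adjusted p 0.0762). All 3 endothelial genes rose, over the list alone too, with Eng at 1.08 ± 0.12, Egfl7 at 0.80 ± 0.10 and Emcn at 0.67 ± 0.13 (adjusted p 0.00114). Of 6 matrix genes 4 rose, 0 fell and 2 did not pass, and 4 rose over the list alone, with Thbs1 at 2.21 ± 0.33, Col5a1 at 1.21 ± 0.23 and Fn1 at 1.19 ± 0.19 (adjusted p 0.0174). Without those 2 libraries, where Tnnc2 was at 329.8 and 158.5 CPM against 0.138 to 56.6 CPM in the others, the matrix list no longer passed (0.0744). Among the rest, muscle transcripts were higher in 3 lean libraries, with Ttn at 106.7, 37.3 and 97.9 CPM in lean 3, 4 and 5, against 1.31 CPM in lean 1 and 0.301 to 6.74 CPM in DIO 1 to 4. With the log2 level of Ttn as a covariate, chosen after the data were seen, 705 genes passed, 662 of them among the 770, and the cholesterol, endothelial and matrix lists were at adjusted p 9.3e-04, 0.00398 and 0.0467. Of 1746 genes 507 rose and 263 fell, against 354 and 488 after rescaling, and 304 passed in a single fit over all libraries, with Ebp (0.281) and Emcn (0.0873) no longer among them.

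**Figure D2:**
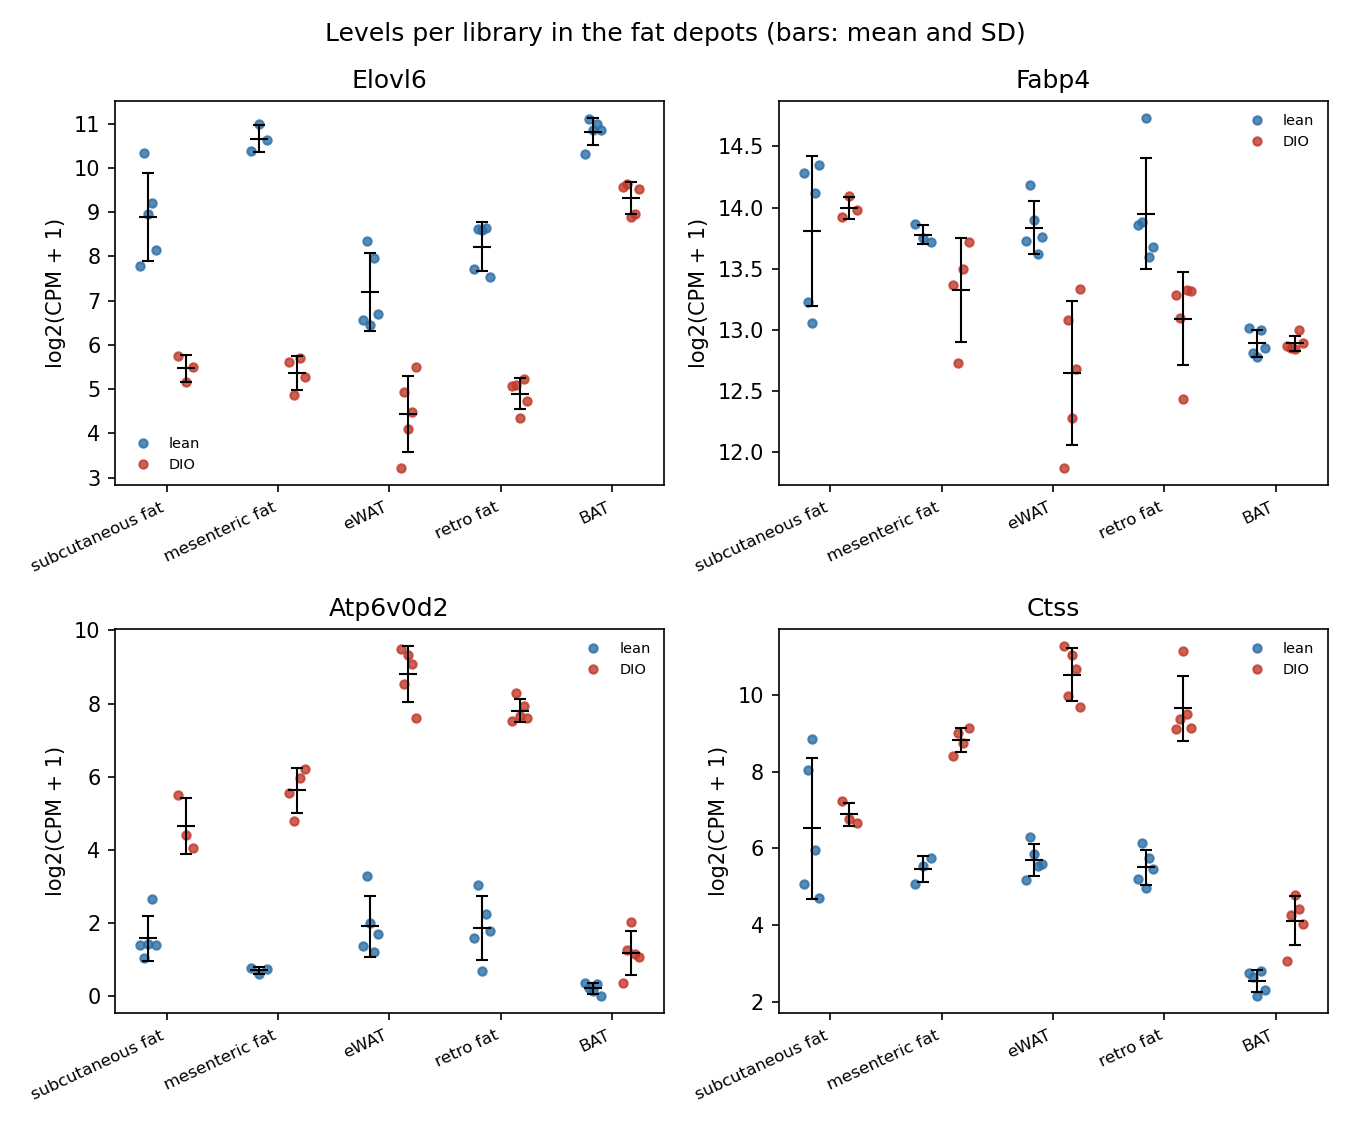
Levels of Elovl6, Fabp4, Atp6v0d2 and Ctss as log2(CPM + 1) in each library of the 5 fat depots, lean in blue and DIO in red, with the mean and SD of each group as a black bar. Elovl6 fell in all 5 depots, whereas Atp6v0d2 rose in the 4 white depots.

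The diet effect differed between the 4 white fat depots for 844 of 2345 genes (interaction test over 35 libraries). After rescaling 749 passed, 588 of them among the 844. Zranb3, a DNA repair translocase, changed by 0.58 in subcutaneous, 1.73 in mesenteric, 4.36 in epididymal and 4.18 in retroperitoneal fat, and averaged 7.67, 16.8, 94.0 and 75.6 CPM in the DIO groups (adjusted p 1.1e-08). Dhrs9, a retinol dehydrogenase, changed by 1.36, 1.31, 5.23 and 4.02 in the same order (1.8e-07), and Rab7b, an endosomal GTPase, by 0.77, 1.87, 4.02 and 3.01 (2.4e-06). Gla, the lysosomal alpha-galactosidase, averaged 12.8, 18.3, 72.9 and 41.0 CPM in the DIO groups and 7.77, 7.11, 6.37 and 6.06 CPM in the lean groups (2.4e-06). The largest change lay in eWAT for 397 of the 844 genes, in mesenteric fat for 187, in subcutaneous fat for 182, and in retroperitoneal fat for 78. The changes of 601 had opposite signs in at least 2 depots (581 after rescaling), whether or not they passed there, and 40 of the 844 passed in opposite directions in 2 depots (18 after rescaling). Without the libraries doubted for their markers 689 genes passed, 581 of them among the 844, and without subcutaneous DIO 1, DIO 2 or DIO 3 the count was 547, 533 and 478. Genes called in 2 depots in the same direction outnumbered chance in every pairing. Thus 618 rises were common to eWAT and retroperitoneal fat where 269 would be met by chance, and 195 falls where 37 would be. Likewise 38 falls were common to subcutaneous and mesenteric fat where 5.80 would be. None of the genes called in both eWAT and retroperitoneal fat moved in opposite directions before rescaling, nor did any called in both mesenteric and retroperitoneal fat. However, 27 genes that rose in mesenteric fat fell in eWAT, and 3 that fell in mesenteric fat rose in eWAT. Of the genes that rose in subcutaneous fat 11 fell in eWAT, 3 in mesenteric fat and 1 in retroperitoneal fat, and 3 that fell in subcutaneous fat rose in mesenteric fat.

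In liver (5 DIO, 5 lean) genes of fatty acid oxidation and xenobiotic metabolism rose and male-biased and bile acid genes fell. Hsd3b5, a steroid enzyme of male mouse liver, fell to 12.4 ± 13.7 from 266 ± 49.3 CPM (-5.20 ± 0.73, adjusted p 5.8e-04), and Cyp7b1, a hydroxylase of the alternative bile acid route, to 101 ± 38.8 from 253 ± 51.5 CPM (-1.44 ± 0.31). Igfbp2 fell to 109.6 ± 52.9 from 339 ± 88.0 CPM and the fatty acid carrier Fabp5 to 14.4 ± 8.11 from 229 ± 61.1 CPM (-4.02 ± 0.30). Lcn2, an acute phase protein, rose to 94.0 ± 168 from 1.39 ± 0.652 CPM (3.78 ± 0.83, adjusted p 0.00701). It was at 393.2 CPM in the DIO 2 library, 7.34 to 40.9 CPM in the other DIO libraries and 0.490 to 2.03 CPM in the lean ones. Without DIO 2 the DIO mean was 19.2 CPM and the log2 difference 2.87, with no test, since the mean of all libraries was then under 10 CPM. The cell surface proteoglycan Gpc1 rose to 61.0 ± 7.68 from 15.4 ± 5.91 CPM. The adenosine receptor Adora1 rose to 65.7 ± 11.3 from 20.7 ± 6.08 CPM and the xenobiotic sensor Nr1i3 to 356 ± 97.2 from 138 ± 47.8 CPM (1.40 ± 0.26). All 4 fatty acid oxidation genes rose, over the list alone too, for example Acadm by 0.74 ± 0.09, Decr1 by 0.60 ± 0.09 and Acadl by 0.46 ± 0.09 (list test adjusted p 0.00176). Of 4 xenobiotic genes 3 rose, 0 fell and 1 did not pass (3 rose over the list alone), Ugt1a1 at 0.65 ± 0.10, Gstm3 at 0.94 ± 0.29 and Ephx1 at 0.54 ± 0.17 (0.0239). After rescaling Ephx1 did not pass (adjusted p 0.0788), nor did Gstm3 with no filter (0.0677). Of 4 bile acid genes 3 fell, 0 rose and 1 did not pass (3 fell over the list alone), with Abcb11, the bile salt exporter, at -0.51 ± 0.11 and Cyp27a1 at -0.35 ± 0.08 (0.00659). Of 3 male-biased genes Hsd3b5 and Cyp7b1 fell and Susd4 did not pass at -0.90 ± 0.37, while 3 fell over the list alone (0.0239). Of 1699 genes 355 rose and 103 fell, against 155 and 209 after rescaling, and 294 passed without the DIO 4 library. A single fit over all libraries gave 139, with Abcb11, Cyp27a1, Ephx1 and Ugt1a1 no longer past the threshold. With an index of 10 genes that parts libraries in 11 tissues as a covariate, chosen after the data were seen, 57 genes passed and none of these 4 lists did.

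Soleus and red gastrocnemius (5 DIO, 5 lean each) showed higher fatty acid oxidation genes. Decr1, which oxidises unsaturated fatty acids, rose by 0.88 ± 0.08 in soleus (adjusted p 6.7e-04) and to 333 ± 33.6 from 169 ± 13.2 CPM in red gastrocnemius (0.97 ± 0.07, adjusted p 1.4e-05). Of 3 tested oxidation genes 2 rose in soleus, 0 fell and 1 did not pass (3 rose over the list alone, list test adjusted p 0.00120), with Acadl at 0.46 ± 0.07. All 3 rose in red gastrocnemius, over the list alone too (1.1e-04), with Acadl at 0.66 ± 0.05 and Acadm at 0.46 ± 0.06. Soleus also gained Dkk2, a Wnt antagonist (70.3 ± 23.5 against 33.6 ± 7.60 CPM, 1.01 ± 0.22), the acyl-CoA binding protein Dbi (0.76 ± 0.08) and the membrane protein Stom (0.74 ± 0.07). It lost Armcx4 (-0.92 ± 0.10) and Myoz2, a protein of slow fibres (754 ± 51.1 against 1017 ± 57.4 CPM, -0.43 ± 0.06). Lower as well was the slow tropomyosin Tpm3 (2908 ± 241 against 3802 ± 221 CPM, -0.39 ± 0.07). The other tested genes of the slow fibre list did not pass. They were Tnni1 at -0.13 ± 0.09, Myh7b at -0.17 ± 0.43 and Casq2 at -0.0075 ± 0.11 (adjusted p 0.651, 0.957 and 0.996). Neither Dkk2 nor Tpm3 passed after rescaling (adjusted p 0.0507 and 0.0517) or with no filter (0.140 and 0.154). Red gastrocnemius gained the myosin-binding protein Mybph (50.6 ± 15.3 against 13.4 ± 5.15 CPM, 1.86 ± 0.25), Stom (0.79 ± 0.08) and catalase, Cat (237 ± 20.7 against 145 ± 10.8 CPM, 0.70 ± 0.07). This muscle lost the spermine oxidase Smox (126 ± 27.8 against 236 ± 45.2 CPM, -0.91 ± 0.15), the lysine methyltransferase Mettl21c (-0.66 ± 0.09), Mlf1 (-0.65 ± 0.09) and Ivd of leucine breakdown (-0.40 ± 0.06). Of 1691 genes 19 rose and 10 fell in soleus (16 and 4 after rescaling), and of 1640 genes 54 rose and 29 fell in red gastrocnemius. A single fit over all libraries gave 5 in soleus and 10 in red gastrocnemius, and did not pass Acadl, Armcx4, Dbi, Myoz2, Stom or Tpm3 in soleus or Acadm, Cat, Ivd or Mlf1 in red gastrocnemius. Ttn, the giant muscle protein titin, was at 6652 to 7075 CPM in replicates 1 and 2 of both diets in soleus and at 13210 to 16130 CPM in the others. With a term for that gap, chosen after the data were seen, 66 genes passed in soleus (34 higher, 32 lower), with all 29 among them, and with the index of 10 genes as a covariate 198 passed in soleus and 33 in red gastrocnemius. Leaving out single libraries gave 18, 17, 18 and 15 in soleus without DIO 3, lean 3, lean 4 and lean 5, and 34, 41, 51, 40 and 39 in red gastrocnemius without DIO 2, DIO 3, DIO 4, lean 2 and lean 5.

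In EDL (5 DIO, 4 lean) only Smox passed out of 1462 genes, at 122 ± 27.6 against 271 ± 41.6 CPM (-1.15 ± 0.17, adjusted p 0.0475). The median shift there was -0.121, and relative to it Smox changed by -1.01 and did not pass (adjusted p 0.226), nor did any gene without DIO 1, DIO 2, DIO 3, DIO 4, lean 1, lean 2 or lean 4. The fat cell gene Fabp4 was at 1020 CPM in the EDL DIO 3 library and at 92.9 to 369.8 CPM in the others. Across the 3 muscles the diet effect differed for 1 of 1767 genes (29 libraries): Mettl21c changed by 0.36 in soleus, -0.66 in red gastrocnemius and -0.85 in EDL (adjusted p 0.0437). It no longer passed after rescaling, where 0 genes did. Nor did it pass without soleus DIO 2, 3 or 4 or lean 2, 3, 4 or 5, red gastrocnemius DIO 2, 3, 4 or 5 or lean 1, 2, 3 or 5, or EDL DIO 1, 2, 3 or 4 or lean 2 or 4, each of which left 0 genes. Conversely, 4 passed without EDL DIO 5 and 2 without EDL lean 1. Stom, at 0.74, 0.79 and -0.04, Atp1b1, a sodium pump subunit, at -0.27, 0.10 and -0.71, and Cd55, a complement regulator, at 0.15, -0.19 and -0.43, came next and did not pass (adjusted p 0.681, 0.681 and 0.753).

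In heart (5 DIO, 5 lean) the membrane glycoprotein Igsf1 rose to 33.5 ± 2.49 from 19.8 ± 2.12 CPM (0.73 ± 0.11, adjusted p 0.0198), a gene named after the values were seen. It was among 2 genes past the threshold out of 1753, while 811 passed with array weights, 13 by DESeq2 and 7 in a single fit over all libraries. Of 4 fatty acid oxidation genes 1 rose, 0 fell and 3 did not pass, while all 4 rose over the list alone (list test adjusted p 0.00114). Decr1 was at 665 ± 25.1 against 395 ± 76.8 CPM (0.78 ± 0.13), Acadl at 0.39 ± 0.11 and Acadm at 0.36 ± 0.08. The lean 5 library had Ndufc1, a subunit of complex I, at 33.5 CPM against 115.1 to 148.5 CPM in the others of this tissue, and 15 genes passed without it, but 1 without any of the rest save lean 4. In the lean 3 library Pck1 was at 257.9 CPM, against 0.0871 to 0.816 CPM in the others. Ttn was at 1933 to 2110 CPM in replicates 1 and 2 of both diets in heart and at 4351 to 5666 CPM in the others, and 3 genes passed with a term for that gap.

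**Figure D3:**
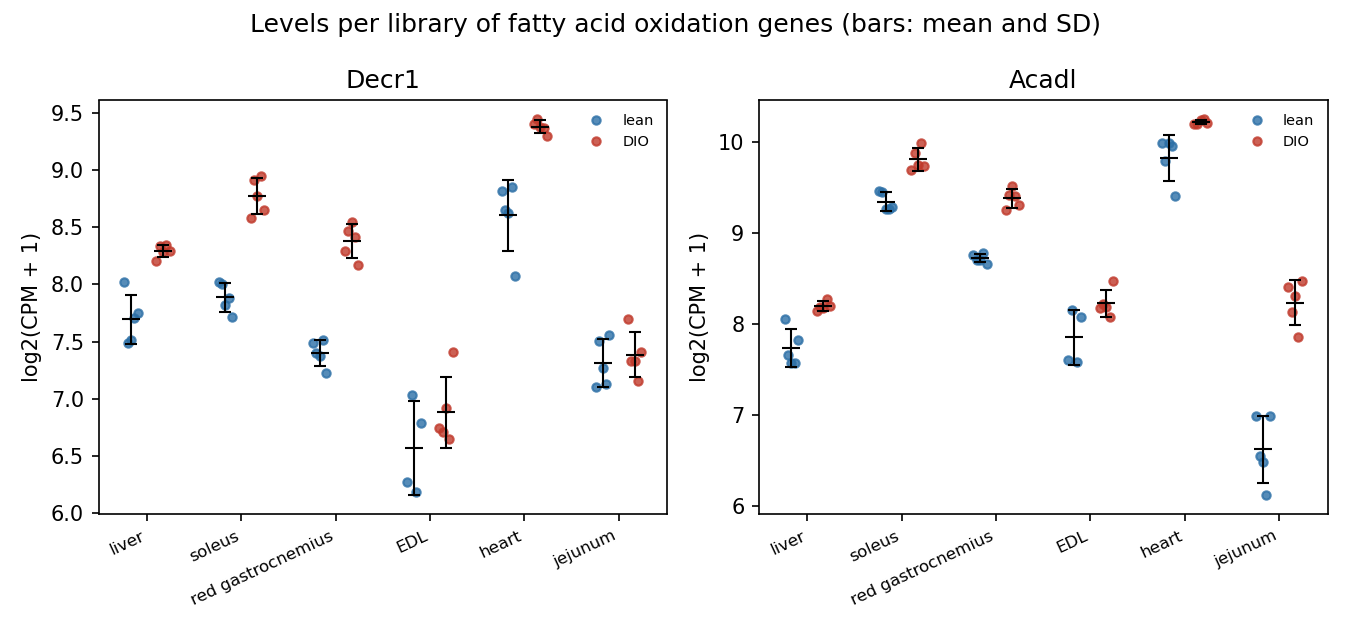
Levels of Decr1 and Acadl as log2(CPM + 1) in each library of liver, 3 muscles, heart and jejunum, lean in blue and DIO in red, with the mean and SD of each group as a black bar. Both genes were higher in every DIO library of liver, soleus, red gastrocnemius and heart than in any lean library of the same tissue.

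In jejunum (5 DIO, 5 lean) 2 of 4 fatty acid oxidation genes rose and 3 of 4 goblet and antimicrobial genes fell. The median shift was -0.124, and changes here are rescaled. Bbox1, the last step of carnitine synthesis, rose to 51.5 ± 20.6 from 2.65 ± 1.26 CPM (3.90, adjusted p 1.6e-05) and the laminin chain Lamb3 to 90.8 ± 24.3 from 15.9 ± 7.41 CPM (2.65). The lactate transporter Slc5a12 rose by 1.78. Mptx2, a pentraxin of Paneth cells, fell to 110.4 ± 67.3 from 541 ± 244 CPM (-2.31, adjusted p 0.0101), and Npl, a sialic acid lyase, to 12.1 ± 5.24 from 59.9 ± 23.7 CPM (-2.13). The riboflavin transporter Slc52a3 fell to 43.1 ± 15.4 from 155 ± 61.0 CPM and Duox2, which makes hydrogen peroxide at the mucosa, to 28.6 ± 9.11 from 71.3 ± 24.4 CPM (-1.18). Of 4 fatty acid oxidation genes 2 rose, 0 fell and 2 did not pass (2 rose over the list alone), with Acadl at 1.71 (list test adjusted p 0.00311 after rescaling). Of 4 goblet and antimicrobial genes 3 fell, 0 rose and 1 did not pass (4 fell over the list alone), with a list test of 0.0179 after rescaling. Of these Duox2 also passed after rescaling, but its partner Duoxa2 (-1.05, adjusted p 0.0845) and Clca1 of goblet cells (-0.77, 0.0963) did not. Of 2021 genes 72 rose and 133 fell, against 77 and 66 after rescaling. This was the highest count of the 4 intestine segments with all libraries, but not without the duodenum lean 3 library (806 in duodenum) or with array weights (429 in jejunum, 795 in duodenum and 530 in colon). The count was 310 without DIO 5, and 95, 54, 88, 74, 111, 65 and 85 without DIO 1, DIO 3, DIO 4, lean 2, lean 3, lean 4 and lean 5.

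In the other segments 6 genes or fewer passed by limma with all libraries weighted alike and each tissue fitted alone. In duodenum (5 DIO, 5 lean; median shift 0.112) 6 of 2075 genes did. Among them were Lamb3 at 69.4 ± 19.6 against 21.9 ± 4.71 CPM (1.44 rescaled, adjusted p 0.0475) and the matrix proteoglycan Bgn at 121 ± 23.1 against 59.7 ± 11.1 CPM (0.85, 0.0475), of which Bgn did not pass with the index of 10 genes as a covariate (0.127). Pxmp4, a peroxisomal membrane protein, did not pass after rescaling (0.51, 0.150). By rank correlation lean 3 was the only duodenum library whose best match was a library of the other diet (DIO 2, 0.989). Without the lean 3 library 806 genes passed in duodenum, 0 passed without DIO 2, DIO 4, lean 2, lean 4 or lean 5, 1 without DIO 3 or DIO 5, and 2 without DIO 1 or lean 1. In ileum (5 DIO, 5 lean) 0 of 2073 genes passed by limma, with 115 at unadjusted p under 0.05, 0 by edgeR, 3 by DESeq2 and 1 without DIO 4. The genes of lowest p were Mptx2 (-2.39 ± 0.46, adjusted p 0.394) and the lipase Aadac (1.37 ± 0.33, 0.846). In colon (5 DIO, 5 lean) 0 of 2222 genes passed by limma, with 422 at unadjusted p under 0.05, 2 by edgeR and 165 by DESeq2. The colon libraries lay in 2 classes by the index of 10 genes (4 DIO and 3 lean in the higher), and 73 genes passed with a term for the class and 81 with the index as a covariate, both chosen after the data were seen. Counts of 2, 1, 16 and 16 passed without DIO 1, DIO 3, DIO 5 and lean 4. Its lowest p belonged to Tpx2, a spindle protein, at 23.6 ± 2.55 against 40.1 ± 7.18 CPM (-0.73 ± 0.12, adjusted p 0.0545), and to G6pdx of the pentose phosphate route at -0.63 ± 0.11 (0.0545). After rescaling 9 genes passed, Tpx2 (0.0265) and G6pdx (0.0393) among them. The 4 proliferation genes fell over the list alone in colon, where 0 passed over all genes, with Ube2c at -0.63 ± 0.13, Cenpf at -0.62 ± 0.19 and Ccna2 at -0.46 ± 0.18 (list test adjusted p 0.0190).

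The diet effect differed between the 4 intestine segments for 355 of 2368 genes (40 libraries). After rescaling 344 passed, 268 of them among the 355. Bbox1 changed by 3.82 in jejunum and by -0.33, 0.03 and 0.05 in duodenum, ileum and colon (adjusted p 4.9e-11). Mfsd4a, a membrane transporter, changed by -2.14 in jejunum (8.26 against 38.8 CPM) and by -0.35, -0.39 and 0.03 in the others (1.7e-06), Npl by -2.23 in jejunum and 0.43, -0.23 and 0.11 (6.1e-06), and Acadl by 1.61 in jejunum and 0.73, 0.46 and -0.22 (6.1e-06). The largest change was in jejunum for 201 of the 355 genes, in duodenum for 135, in colon for 16 and in ileum for 3. Leaving out duodenum lean 3 gave 773 genes, and leaving out duodenum DIO 2 gave 210 and duodenum lean 1 222.

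In stomach (lesser curvature; 5 DIO, 5 lean; median shift 0.201) 1 of 2029 genes passed: Nnat, an imprinted membrane protein, at 23.0 ± 8.75 against 2.44 ± 1.13 CPM (rescaled 2.61, adjusted p 0.0114). The gene of next lowest p was Myoz2 at -2.04, which did not pass (adjusted p 0.146), and without the DIO 2 library 2 genes passed. Array weights gave 1212 genes in stomach, a single fit over all libraries 336 and DESeq2 18. Interferon genes were higher in the list test (adjusted p 0.0391), with 2 of 3 past the threshold over the list alone and 0 over all genes. Ifih1 was at 0.42 and Gbp2 at 0.44 relative to the shift, and the list did not pass after rescaling (0.0701), with no filter (0.212) or with a term for the library class (0.0553).

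No gene passed in any of the 4 brain regions (5 DIO, 5 lean each). In hypothalamus, out of 2457 genes, limma gave 0 with 54 at unadjusted p under 0.05, and edgeR and DESeq2 gave 0 and 0. The feeding peptides there were Avp (vasopressin) at 26.5 ± 16.2 against 21.8 ± 20.6 CPM (0.98 ± 1.15, adjusted p 0.845) and Oxt at 25.5 ± 19.4 against 22.7 ± 22.9 CPM (0.53 ± 1.26, 0.926). Bdnf was at 17.7 ± 3.18 against 18.7 ± 5.78 CPM (-0.04 ± 0.20, 0.985). The lowest p belonged to Pax6 (-0.26 ± 0.06, adjusted p 0.842) and Chchd7 (-0.17 ± 0.04). In cerebral cortex 0 of 2333 genes passed by limma, edgeR and DESeq2, with 66 at unadjusted p under 0.05, Arhgap6 at -0.91 ± 0.23 (adjusted p 0.842) and Diexf at 0.28 ± 0.09. In midbrain and brainstem 0 of 2383 passed by all 3 tools, with 19 unadjusted, Fbn1 at -0.40 ± 0.12 (adjusted p 1) and the serotonin receptor Htr2c at -0.18 ± 0.06. In cerebellum 0 of 2391 passed by all 3, with 16 unadjusted and Mfsd4a at -0.30 ± 0.09 (adjusted p 1). The diet effect differed between regions for 0 of 2621 genes (limma, 40 libraries, 35 at unadjusted p under 0.05). The lowest p were those of Arhgap6 (0.16, -0.91, -0.05 and 0.32 in the order above), Trpm7 (0.01, 0.17, -0.13 and -0.10), Mfsd4a (0.20, 0.07, 0.04 and -0.30) and Pbx3 (-0.06, -0.42, -0.04 and 0.23), each at adjusted p 1.

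In kidney (5 DIO, 5 lean) 1 of 1979 genes passed, the fibrillar collagen Col5a2 at 14.2 ± 0.821 against 25.9 ± 4.40 CPM (-0.81 ± 0.10, adjusted p 0.0127), and the secreted peptide Prok1 lay just outside at -0.83 ± 0.14 (0.0539). Most tested genes of the extracellular matrix list went the other way. Col3a1 was at 0.69 ± 0.15, Fn1 at 0.43 ± 0.13, Col6a3 at 0.48 ± 0.17 and Col5a1 at 0.41 ± 0.16, but Thbs1 at -0.30 ± 0.21. None of these passed over all genes (adjusted p 0.0908 to 0.551), and each but Thbs1 did over the list alone. Genes of gluconeogenesis and insulin action were higher in the list test (adjusted p 0.0286), with 0 of 4 past the threshold over all genes and 1 over the list alone. Its members were Pck1 at 2361 ± 386 against 1638 ± 490.1 CPM (0.56 ± 0.19), Slc2a2 at 0.24 ± 0.10, Foxo1 at 0.14 ± 0.06 and Irs1 at -0.00 ± 0.08. The list did not pass after rescaling (0.102), with no filter (0.0549) or without the lean 3 and lean 5 libraries (0.0672), in which Elovl6 was at 50.7 and 59.0 CPM against 10.1 to 17.0 CPM in the other kidney libraries. By DESeq2 89 genes passed in kidney, with array weights 24, and after rescaling 13, with Col5a2 not past the threshold in a single fit over all libraries (adjusted p 0.999). Single libraries left out gave 3, 0, 2, 7, 4, 0, 5 and 5 genes in kidney without DIO 1 to 5, lean 1, lean 3 and lean 5.

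In adrenal (5 DIO, 5 lean) 3 of 2343 genes passed. Elovl6 fell to 68.7 ± 31.3 from 776 ± 340.1 CPM (-3.51 ± 0.40, adjusted p 0.00805), and Tmem79 (-3.03 ± 0.42, 0.0205) and 1700037H04Rik, which fell as well, were named after the values were seen. The median shift was 0.13, and relative to it Elovl6 changed by -3.67 and 0 genes passed (Elovl6 adjusted p 0.0601), and 0 passed by edgeR, but 88 by DESeq2, 96 with array weights and 677 in a single fit over all libraries. Each of the 3 genes also fell in subcutaneous, mesenteric and retroperitoneal fat, and the fat cell gene Fabp4 was at 3030 ± 2496 against 4788 ± 2694 CPM in adrenal (adjusted p 0.674). Without the DIO 1, DIO 2 and lean 1 libraries, in which Hsd3b1 was nearly absent, 12 genes passed, and 1 passed without DIO 1, DIO 2, DIO 3, lean 2, lean 3 or lean 4 alone.

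Some genes changed in 5 or more tissues. Elovl6 fell in 7 tissues, the 5 fat depots, liver (-0.79 ± 0.22) and adrenal, where libraries held Fabp4 of fat cells and the call ended after rescaling (adjusted p 0.0601). Acss2 fell in 6, the fat depots and jejunum (-0.65 ± 0.15, rescaled -0.55). Mr1, which presents microbial vitamin metabolites to T cells, fell in the 5 fat depots, liver and red gastrocnemius, with -0.97 ± 0.14 in brown fat and -0.44 ± 0.14 in liver. Lamb3 rose in 7 tissues, for example at 18.4 ± 5.63 against 3.57 ± 1.13 CPM in liver and 1.44 ± 0.15 in brown fat. Rises in 6 tissues were those of Gpc1 (2.16 in subcutaneous and 2.13 in brown fat), the Rac exchange factor Prex1 (1.12 in liver) and Fam129b (1.15 in brown fat). Others were Lbp (0.65 in liver and 0.75 in soleus), Prelp (0.44 in liver), Bgn (1.45 in brown fat), Col6a3 (0.80 in liver) and Trp53inp2 (0.25 in liver). Gpc1 fell in red gastrocnemius (-0.20 ± 0.05, adjusted p 0.0451, and 0.0887 after rescaling), and after rescaling the rises of Lbp in eWAT (0.0508) and of Prelp (0.0896), Col6a3 (0.0574) and Trp53inp2 (0.289) in liver did not pass. In all, 98 genes passed in the same direction in at least 5 tissues, 72 higher and 26 lower, where shuffling the calls within tissues gave 14.4 on average and 25 at most (permutation p 0.001, the smallest that 1000 shuffles can give). The shuffle treats tissues as independent, and it also breaks the overlap of calls among the 5 fat depots given above. Its p therefore does not tell sharing beyond fat from sharing within fat. Genes shared by at least 7 tissues numbered 3. After rescaling 58 genes were shared, 26 higher and 32 lower, and by edgeR 59 (26 and 33), while 227 were shared without the libraries doubted for their markers (168 and 59) and 758 with array weights (636 and 122).

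Among the pairs of a fixed gene list and a tissue, 128 had at least 3 tested members, and 28 passed by limma's fry (20 higher in DIO, 8 lower). Fry asks whether the members move on balance in 1 direction and does not compare them with other genes. When values were rescaled within the tissue 25 pairs passed, 23 of them among the 28. An exact permutation test over the libraries passed 0 of 128, its smallest p being 0.00794, the smallest that 5 against 5 libraries can give. Adjusted over 128 pairs, a p at that floor passes only if many pairs share it, so this count decides little.

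Among lists with too few tested members for fry, the 2 fatty acid synthesis genes Elovl6 and Acss2 both fell in all 5 fat depots, over the list alone too. The unfolded protein response genes Atf3 and Hspa5, the only 2 tested, rose in mesenteric fat, eWAT and retroperitoneal fat, over the list alone too. Rescaled changes were 2.56 and 0.22 in mesenteric fat, where Hspa5 no longer passed (adjusted p 0.392), and they were larger in eWAT (5.26 and 0.86) and retroperitoneal fat (4.32 and 0.58). The 2 tested proliferation genes, Tpx2 and Ccna2, rose in eWAT (3.05 and 2.33) and retroperitoneal fat (2.29 and 2.15), over the list alone too.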

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

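The tests of diet on the adrenal libraries, on the library classes and on the index, and the ratio of Elovl6 to Fabp4, were chosen only after the result was seen. Values that lay far from the rest of their group were met 12 times among the library totals and named genes tested. About 1 in 20 would be met by chance, which is 10.2 here, so their number is near that of chance. Of these 3 lie in the lean eWAT libraries, and 2 in libraries already doubted for other reasons. Library totals in M reads stood apart in mesenteric fat DIO 4 (30.9, others 25.9 to 26.5), soleus lean 5 (29.1, others 24.5 to 25.6) and red gastrocnemius lean 5 (20.0, others 25.3 to 26.4). So did heart lean 5 (19.5, others 24.1 to 25.4) and colon DIO 5 (12.0, others 18.3 to 20.7). Rgs1 was at 5.73 CPM in eWAT lean 2 (others 0.361 to 0.924), Il1rn was at 1.88 CPM in the same library (others 0.53 to 0.72), and Pck1 was at 3819 CPM in eWAT lean 5 (others 1694 to 2105). Acss2 was at 75.0 CPM in retroperitoneal fat DIO 3 (others 172.4 to 203) and Cyp7b1 at 34.1 CPM in liver DIO 3 (others 102.6 to 130.1). Mettl21c was at 44.6 CPM in red gastrocnemius DIO 1 (others 34.5 to 36.8) and Lamb3 at 133 CPM in jejunum DIO 1 (others 73.3 to 87.0). The diet effect differed between related tissues for 844 genes in white fat, 1 in muscles and 355 in the intestine.

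In adrenal DIO 1, DIO 2 and lean 1 Hsd3b1 was nearly absent. Nr5a1, Nr0b1 and Dbh, which mark adrenal cortex and medulla, had in these 3 libraries a median of 0.210% of the lowest level in the other 7 (Nr5a1 at most 0.292 against at least 139 CPM, Dbh 0.135 against 41.5, Nr0b1 0 against 1.96). Fabp4 lay at 2871 to 8633 CPM in them and 1184 to 6519 CPM in the rest, ranges that overlap. Their closest libraries were retroperitoneal fat DIO 4, eWAT DIO 2 and retroperitoneal fat lean 4 (rank correlation 0.9035, 0.9857 and 0.9584). Fat in place of adrenal is thus a likely content, less surely in DIO 1, whose match was the weakest of the 3. A diet effect on the adrenal as the whole cause is argued against by 4 libraries, since lean 1 lacked Hsd3b1 while DIO 3, DIO 4 and DIO 5 had it at or above the lowest of the other lean libraries. Which mouse or dissection they came from stays open.

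Libraries of 11 tissues fell into 2 classes by the index of 10 genes. Differences between the classes were alike over tissues to a varying degree (correlation across genes 0.205 to 0.854, median 0.593). This correlation and the genes described below leave out the index genes, and also cerebral cortex and midbrain and brainstem, which served to pick them. Adrenal was kept, with DIO 2 and lean 1, which lacked Hsd3b1, in its lower class. Diet as the whole cause is argued against, since both classes held both diets in all 11 tissues. In adrenal this rests on DIO 2, the only DIO library of the lower class there, which likely held fat. Without the libraries lacking Hsd3b1, the lower class of adrenal held only lean 2 and lean 5. A partial tie stays open, as the groups are small and some were uneven, such as cerebral cortex (3 DIO and 1 lean in the higher class) and jejunum (2 DIO and 4 lean). The genes described were over 2-fold apart between classes, the same way in at least 3 of the tissues kept. Their exon length, merged over all annotated transcripts of a gene, was short. Its median was 0.390 of that of all tested genes (1951 against 5007 bases, resampling p 3.0e-05). These genes also more often had a pseudogene named after them (10.6 times, 23.1% of 13 against 2.19% of 2426, Fisher p 0.00241). A step of the library preparation or of read assignment could set such genes apart, which was not tested. Of the 13, Rpl37a, Rpl10, Rps20, Rps21 and Rps27 are ribosomal protein genes, and Rpl10 and Rps27 have a named pseudogene. These values do not tell length or pseudogenes apart from that family. Overlap with a gene on the opposite strand was 0.253 times as frequent as among all tested genes (exact 95% interval up to 1.18, under the 1.2 set beforehand). Of the 13 genes only Sdhaf4 has such an overlap, so these genes are too few to decide. Overlap on the same strand stays open as well (2.16 times, 0.269 to 6.37). These overlaps were judged in 3 ways, the last 2 chosen after the values were in view: by the ratio alone, by Fisher p under 0.05, which left both open (0.126 and 0.236), and by the interval. The library identifiers of the 11 parted tissues were all higher in number than those of the 10 others. The classes thus go with a part of the series, and what parted the libraries within those tissues stays open. In the 10 tissues without 2 classes the largest differences of the index between diets (DIO minus lean) were 0.663 in heart (exact permutation p 0.302; 0.141 without lean 5), -0.332 in duodenum (p 0.0873), -0.296 in liver (p 0.00794) and 0.247 in soleus (p 0.0635). None passed when adjusted over the 10 (0.393, 0.291, 0.0794 and 0.291). However, the p of liver is the smallest that 5 against 5 libraries can give. It could not pass over 10 tissues unless another tissue reached it too. The index of every DIO liver library (0.258 to 0.503) lay under that of every lean one (0.582 to 0.926).

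Elovl6 fell in the visceral fat of DIO mice while genes of macrophages rose, so fewer adipocytes per RNA might account for the fall. Against this, Elovl6 over the adipocyte gene Fabp4 changed by -2.96 on average (-1.57 in eWAT, -2.46 in retroperitoneal fat, exact permutation p 0.00794 in each, and -4.85 in mesenteric fat, p 0.0286). Over Acvr1c, a receptor of adipocytes, it changed by -2.34 on average (-1.97 in retroperitoneal fat, p 0.00794; -4.43 in mesenteric fat, p 0.0286), but by -0.63 in eWAT (p 0.397), where part of the fall could be of this kind. A fall of Elovl6 per adipocyte is a hypothesis for mesenteric and retroperitoneal fat and stays open for eWAT.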

How the results depend on the processing

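Leaving out the doubted libraries, the index covariate, the class term and the Ttn terms were chosen only after the result was seen. Of 180 named gene changes, 1259 values under the alternatives set in advance stayed the same in 1155, weakened in 56, strengthened in 43 and reversed in 5. With 1 library left out, 1562 of 1688 stayed the same, 93 weakened, 18 strengthened and 15 reversed. No value could be had where the mean fell under 10 CPM, for Lcn2 in liver without DIO 2, Duoxa2 in jejunum without lean 3 or lean 5, Thbs1 in brown fat without DIO 2 or DIO 3 and Zbp1 in mesenteric fat without DIO 2, nor from DESeq2 for Lcn2 in liver. Counts of genes moved more. No paired analysis was made, because replicate numbers follow the order of deposit and no label ties them to mice. In soleus and heart the numbers do go with the gap of Ttn given above. The cause was not tested for any of these moves. The groups of 3 to 5 libraries, and a table with 23.7% of genes, limit what the counts can say.

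DESeq2 gave 4 genes in EDL, 88 in adrenal, 165 in colon, 114 in duodenum, 13 in heart, 3 in ileum, 309 in jejunum, 89 in kidney, 151 in red gastrocnemius, 68 in soleus, 18 in stomach and 551 in subcutaneous fat. edgeR gave 0 in EDL, 0 in adrenal, 2 in colon, 4 in heart, 557 in mesenteric fat, 0 in the muscle interaction and 59 genes shared by at least 5 tissues. Array weights gave 96 in adrenal, 530 in colon, 795 in duodenum, 811 in heart, and 429 in jejunum. They also gave 24 in kidney, 1580 in mesenteric fat, 130 in red gastrocnemius, 1212 in stomach, 946 in subcutaneous fat, 1082 in the intestine, 154 in the muscle and 1476 in the white fat interaction, and 758 genes shared across tissues. A single fit over all libraries gave 304 in brown fat, 6 in EDL, 677 in adrenal, 9 in colon, and 328 in duodenum. It also gave 7 in heart, 4 in ileum, 402 in jejunum, 4 in kidney, 139 in liver, 10 in red gastrocnemius, 5 in soleus, 336 in stomach and 610 in subcutaneous fat. With no filter, EDL had 0, jejunum 82, midbrain and brainstem 1, red gastrocnemius 48, soleus 18, the brain interaction 8 and the lists 44. Rescaling gave 0 in EDL, 0 in adrenal, 9 in colon, 11 in duodenum, 13 in kidney, 561 in mesenteric fat, 0 in the muscle interaction and 58 shared genes. The exact permutation test called 0 lists, a count limited by the smallest p it can give. Shared genes numbered 342 in at least 4 tissues and 3 in at least 7.

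With the index as a covariate, liver went from 458 to 57 genes, soleus from 29 to 198 and red gastrocnemius to 33, and counts were 3 in EDL, 81 in colon, 3 in duodenum, 8 in heart, 7 in kidney and 2 in the muscle interaction. The index itself differed by -0.296 between DIO and lean in liver (exact permutation p 0.00794, the smallest possible there, adjusted over 10 tissues 0.0794). Its genes Rpl22l1 and Rpl39 were among ribosomal protein genes that fell in liver. There the covariate may take out part of the diet effect, or the diet effect may hold part of a technical one, and the 57 genes cannot settle which. The class term, set after that result was in view, gave 0 in EDL and 73 in colon, and the Ttn term 66 in soleus and 3 in heart. The level of Ttn as a covariate in brown fat gave 705 there. Without the doubted libraries there were 0 genes in EDL, 12 in adrenal, 8 in heart, 20 in kidney, 1505 in mesenteric fat, 972 in subcutaneous fat and 227 shared genes. The count stayed near its value there in brown fat (675), retroperitoneal fat (797), soleus (24), the white fat interaction (689) and the lists (25).

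With 1 library left out in turn, the lowest and highest counts were 662 and 770 in brown fat, 1055 and 1208 in eWAT, 813 and 955 in retroperitoneal fat, 443 and 1505 in mesenteric fat, 64 and 357 in subcutaneous fat, 294 and 434 in liver, 15 and 24 in soleus, and 34 and 104 in red gastrocnemius. They were 0 and 1 in EDL, 1 and 15 in heart, 1 and 2 in stomach, 0 and 806 in duodenum, 54 and 310 in jejunum, 0 and 1 in ileum, 0 and 16 in colon, 0 and 7 in kidney, and 1 and 3 in adrenal. These counts were 0 and 0 in each brain region and in the brain interaction, 210 and 773 in the intestine, 0 and 4 in the muscle, and 478 and 1079 in the white fat interaction.

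Log2 changes that reversed were those of Ebp in mesenteric fat (-0.37 rescaled, -0.34 with edgeR, -0.33 with DESeq2), Ifih1 there (-0.016 rescaled), Ephx1 and Gstm1 in liver (-0.093 and -0.35 with the index) and Lcn2 in eWAT (0.31 with the index, 0.13 with the class term). With 1 library left out, Lcn2 in eWAT ranged from -0.67 to 0.61, with 0.06, 0.61 and 0.40 without DIO 1, lean 1 and lean 3. Hsd17b7 in mesenteric fat ranged from -0.38 to 0.18, with 0.01 without DIO 4. Decr1 in jejunum ranged from -0.006 (without DIO 1) to 0.13, and Irs1 in kidney from -0.037 to 0.05, with 0.01, 0.02, 0.01, 0.05 and 0.01 without DIO 1, DIO 2, lean 1, lean 4 and lean 5. In hypothalamus Bdnf was at 0.092 with array weights and ranged from -0.16 to 0.07, with 0.03, 0.07 and 0.07 without DIO 1, lean 4 and lean 5, and Oxt from -0.28 (without lean 4) to 1.43. None of these changes had passed the threshold for a gene over all genes but Ephx1 and Ifih1.

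Other splits of the same libraries were called the same way, and the number of splits with at least as many genes, the true split included, is given with the highest other count. No other split was as large in subcutaneous fat (56 splits, 274 genes, highest other 137), mesenteric fat (35, 1002, 246) or eWAT (100, 1166, 1). Nor was any in retroperitoneal fat (100, 957, 1), brown fat (100, 770, 32) or liver (100, 458, 4). The same was so in red gastrocnemius (100, 83, 29) and jejunum (100, 205, 49). Chance is argued against there, but 1 of 35, 56 or 100 is the smallest share these splits can give. The shares were not adjusted over the tissues and interactions tested. For the white fat (844, highest other 115) and intestine (355, 160) interactions and the lists (28, 3), 1 of 100 permutations was as large. These permuted diet within each tissue, which breaks any sharing of mice between tissues, so chance is argued against there only if the tissues are independent. For the shared genes (98, highest other 0 in 100 permutations) the permutation decides nothing, since permuted labels called a median of 0 genes in each tissue and so could hardly give a gene called in 5 of them. Adrenal (3 of 100, highest other 528), soleus (4 of 100, 243) and duodenum (4 of 100, 1059) lay under 5% as well, yet other splits called far more genes, which speaks to the structure of the samples. In duodenum the largest of these splits set lean 3 with DIO 2 to 5, and DIO 1 with the other lean libraries. In soleus and heart the largest of these splits set replicates 1 and 2 of both diets, which were low in Ttn, apart together with 1 more library. Chance cannot be excluded in EDL (5 of 100, highest other 374), heart (5, 607), stomach (5, 886), kidney (5, 18) and the muscle interaction (28, 573). With 0 genes, 100 of 100 splits were as large in ileum (highest other 224), colon (0), hypothalamus (99), cerebral cortex (543), midbrain and brainstem (928), cerebellum (934) and the brain interaction (743). In ileum, cerebral cortex, midbrain, cerebellum and adrenal the largest of these splits followed the library class in 90% of libraries.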

Other observations

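The lists of gene families in this part were chosen only after the result was seen, and of 154 tests over 10 such lists (Fisher's exact test against the other tested genes of the tissue, adjusted over the 154) 24 passed. These lists also hold members of the lists fixed in advance, so part of each count repeats genes described above. Their p-values are therefore no independent test of the families. Myeloid genes rose in 25 of 26 tested members in mesenteric fat (9.88 by chance, adjusted p 1.3e-08), 29 of 29 in eWAT (10.5 by chance, 4.7e-12), 29 of 29 in retroperitoneal fat (10.2 by chance, 2.2e-12) and 4 of 4 in brown fat (0.0452), and in 0 of 20 in subcutaneous fat, where their median log2 change was -0.008. Without the lean 2 and lean 3 libraries of that depot, in which Cr2 was high, 10 of 15 rose there as well (4.67 by chance, p 0.0256 adjusted over all such tests without doubted libraries, median 0.914). Matrix genes rose in 7 of 18 in subcutaneous fat, 14 of 19 in eWAT and 13 of 15 in brown fat, the 14 in eWAT including all 7 of the fixed list. Lipid genes fell in 5 of 27 in subcutaneous fat, 10 of 27 in mesenteric fat, 10 of 27 in retroperitoneal fat and 11 of 24 in brown fat, and rose in 14 of 27 in liver, 5 of 19 in soleus and 7 of 17 in red gastrocnemius. Other lipid genes rose, 2 in subcutaneous fat (list median 0.19), 2 in mesenteric, 3 in retroperitoneal and 4 in brown fat, and 3 fell in liver. In eWAT 10 of 27 fell and 6 rose, and the fall did not pass (adjusted p 0.0807). Respiratory chain genes fell in 6 of 17 in subcutaneous fat, 14 of 17 in mesenteric fat, 14 of 17 in eWAT and 6 of 17 in retroperitoneal fat, and rose in 4 of 17 in red gastrocnemius.

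Ribosomal protein genes fell in liver in 16 of 16 tested members (0.970 by chance, adjusted p 1.6e-18, median log2 change -0.35). The genes Rpl22l1 and Rpl39 of the 10-gene index are among them, and so are 5 of the 13 genes that differed between the library classes (Rpl37a, Rpl10, Rps20, Rps21 and Rps27, each higher in the higher class). The index differed by -0.296 in liver, so a technical part of this fall stays open. Proteasome genes fell in 7 of 11 in brown fat. Glutathione and flavin genes fell in 10 of 12 in eWAT (2.3e-05) and 5 of 10 in retroperitoneal fat, and rose in 9 of 17 in liver (0.0236).

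In soleus DIO 1 the epidermal gene Lor was at 226.9 CPM, against 0 to 0.168 CPM in the other soleus libraries.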
